A study of Homo sapiens with 28 samples.

How the data were processed

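RNA had been isolated from bone marrow supernatant with the miRNeasy kit and labelled with Cy3 from 100 ng of total RNA, per the labels' protocols. Images were read with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes; per the file headers, 9 myeloma arrays were read with version 10.7.1.1. The spot files and the files with 1 value per miRNA hold linear intensity values without scaling between arrays: per the file headers, the processed signal is the background-subtracted spot intensity after spatial detrending, and the total signal is its sum over the probes of a miRNA. The authors' deposited table for the whole series holds log2 values of unstated scaling. Set against the scanner files, it equalled the log2 of the total signal for all 8109 detected values of 829 miRNAs within 0.05, with no shift on 22 arrays and a constant downward shift on 6 myeloma arrays, from -0.41 to -3.85. Its column medians were 0 for every control array and between -2.67 and 0 for myeloma arrays. What the shifts were made for stays unknown. 69 names occur more than once in that table with other values, and the first occurrence was used. 19 of the 848 shared miRNAs were not named in it.

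Samples were grouped by the phenotype in their labels, 8 control and 20 myeloma. The headers showed 6 slides, 3 print designs, 2 scanners and 4 scan days. Only the 2362 probes for human miRNAs present on all 3 designs were used; they cover 848 miRNAs, against 887 on the design of the control arrays. Names are those of the control arrays' design, and 63 probes carry another name on another design. Control spots and outlier-flagged spots were left out (25221 of 379904 spots, 6.64%); for 1 probe on 1 array every spot carried an outlier mark and these were kept. Saturated spots were kept (108 over all arrays). A probe counted as detected where at least 50% of its spots were well above background, and a miRNA where any of its probes was.

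The processed signal was divided by the 75th percentile, on each array, of the 155 probes detected on all arrays. It was then set to a floor of 0.00862, the median over arrays of the lowest scaled signal well above background, and log2 was taken. Spots of a probe were averaged. Of several probes of a miRNA the one with the highest mean over all arrays was used; of the 136 miRNAs past the threshold that had another detected probe, 13 had one that went the other way. miRNAs detected on at least 50% of the arrays of a group were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 306 miRNAs and a threshold of 0.05. The floor can make fold changes near it smaller than the true change. Such fold changes also depend on the background correction, and some decreases near the floor changed sign with normexp background correction. Whether a fold near the floor is too small or too large is therefore not known. Where no array of a group measured a miRNA, the fold is set against the lowest signal well above background on each array of that group. Signals of the other group below the floor entered at the floor, so that this fold is not a strict lower bound. Lists of miRNAs for cell types, families, genomic clusters and array behaviour, 23 in all, were fixed before the data were examined; the 17 with at least 4 tested members were tested with camera at a preset correlation of 0.01. Random blocks were fitted with duplicateCorrelation, and for lists the data were decorrelated by the same estimate before camera. The shift that a difference in signal predicts was resampled 2000 times, with arrays drawn again within each group. The number of detected miRNAs and the 75th percentile were compared by exact permutation over all 3108100 ways of choosing 8 of 28 arrays.

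The miRNAs named in the text were chosen by a rule fixed before the data were examined: the 10 largest increases and 10 largest decreases past the threshold among miRNAs detected on at least 50% of the arrays of both groups, up to 5 in each direction among those detected on fewer in 1 group, up to 4 members per list with the smallest adjusted p, and 10 miRNAs named in advance. Some miRNAs that the rule chose are not named in the text, or are not among the 62 named miRNAs counted as past the threshold. No array had the same values as another, and the highest correlation between 2 arrays was 0.985. The model was tested on simulated data with 60 of 306 miRNAs changed, drawn with the means and spread of the arrays (20 sets). It recovered 60.5% of 2-fold, 95.2% of 4-fold and 99.0% of 8-fold changes, with 2.8 false calls per set, and camera found the moved list in 100% of the sets. These sets held no slide or scan day effects, so that 2.8 is not the number of false calls to expect in this design. With scan day effects and no difference between phenotypes the main test made a median of 107 calls in 100 simulated sets (range 83 to 135). There the scan day effects were drawn independently for each miRNA.

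Alternatives were normexp background correction with an offset of 50, which was run on the median spot and background intensities because these are the columns the files hold, the total signal, other scalings, the mean over probes, other detection filters and floors, random and fixed blocks, other variance models, subsets of arrays by design, scanner and slide, the deposited log2 table, and a Wilcoxon test. Scan day as a random block, the contrasts per scan day, the simulations with scan day effects and the run without the dimmest control array were added after the data were examined. Entries for viral miRNAs were kept out of the tests. No probe sequences were used here, so the GC content of probes and cross-hybridisation between family members were not checked. No genomic coordinates are given since the builds named in the headers differ between designs.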

Results

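MicroRNAs (miRNAs, short RNAs that repress the messenger RNAs they bind) were measured in RNA from the fluid part of bone marrow, the supernatant left after the cells are removed, in 8 control samples and 20 samples from multiple myeloma, a cancer of the plasma cells of the marrow. Each sample was hybridised to 1 Agilent human miRNA array in 1 colour (Cy3), from 100 ng of labelled total RNA. The labels do not say whether the samples came from separate donors or what the control samples were, so the p-values measure the spread between these samples. The 28 arrays covered 848 human miRNAs in common, of which 306 were detected on at least 50% of the arrays of a group and were tested. The number of arrays limits the precision of every value.

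The arrays had been read on 4 scan days, named here A to D. Day A held all 8 control arrays on 1 slide. Day B held 4 myeloma arrays, day C held 9 and day D held 7, so that no slide and no scan day carried both groups. Day B used another scanner, and the arrays of days B and D had other print designs than those of days A and C. A comparison of the groups within a batch was therefore not possible, and slide entered the model as a random block beside the main result. Day A and day C shared the print design and scanner, which gave a comparison of 8 control with 9 myeloma arrays. It still followed software version, since all day C arrays had been read with Feature Extraction 10.7.1.1 and all day A arrays with 10.7.3.1. The mean signal of the negative controls lay between 0.0996 and 0.725 on day A and between -1.16 and -0.195 on day C.

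The number of miRNAs detected per array was compared before any scaling. A control array detected 248 ± 27 miRNAs (SD, n = 8) and a myeloma array 269 ± 70.1 (SD, n = 20). The difference of 20.9 miRNAs was smaller than the spread between arrays (2-sided exact permutation test, p = 0.427). Myeloma arrays ranged from 152 to 420 detected miRNAs and control arrays from 183 to 269. The 75th percentile of signal used for scaling was 502 ± 106 (SD, n = 8) in the control group and 664 ± 572 (SD, n = 20) in the myeloma group, and this difference did not pass the test either (2-sided exact permutation test, p = 0.476). Local background lay between 14.9 and 23.3 on the same intensity scale. 1 control array was dim, and without it, a choice made after the data were examined, the difference in detected miRNAs was 11.6 (exact permutation p = 0.671). On the print design shared by both groups the difference was 54.4 (exact permutation p = 0.0748).

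**Figure D1:**
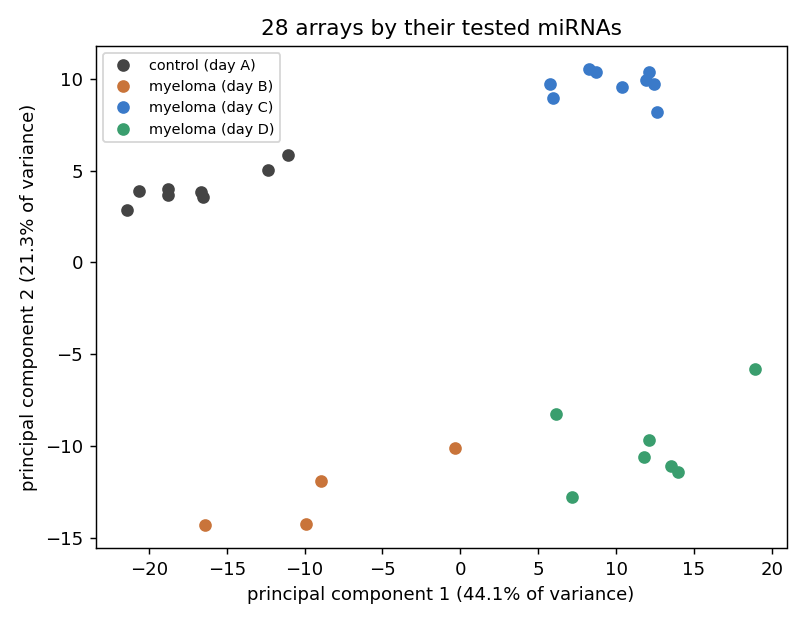
Principal components 1 (x axis, 44.1% of the variance) and 2 (y axis, 21.3% of the variance) of the 306 tested miRNAs, 1 point per array, coloured by scan day. On component 1 the control arrays lie between -21.4 and -11.1, and the 4 myeloma arrays of day B between -16.4 and -0.3, a range that overlaps theirs only in part. Days C and D lie between 5.7 and 18.9. On component 2 days B and D lie between -14.3 and -5.8, and days A and C between 2.8 and 10.6.

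The main comparison asked which miRNAs differed in abundance between myeloma and control marrow fluid. Members of the let-7 family, which are abundant in differentiated cells and repress RAS genes, were lower in myeloma, as were miR-195, miR-34a, a target gene of p53, and the stromal miR-214. Higher in myeloma were miR-198, miR-939, miR-936, miR-940, miR-575 and miR-135a*. Of the 306 tested miRNAs, 191 passed the threshold in limma with Benjamini-Hochberg adjustment, 94 of them higher and 97 lower in myeloma. With slide as a random block (a correlation of 0.535 within slides) the count was 11, with 4 higher and 7 lower, and with scan day as a random block, a choice made after the data were examined, it was 0, with 56 at an unadjusted p under 0.05. Scaling to the median of the probes detected on all arrays moved the split to 79 higher and 124 lower, since the median difference over all tested miRNAs was then -0.30 on the log2 scale against -0.03 in the main scaling.

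Among miRNAs detected on at least 50% of the arrays of both groups, the largest decrease was that of miR-195, which was at -0.53 ± 0.75 (SD, n = 8) in control and -5.09 ± 2.02 (SD, n = 20) in myeloma, on a log2 scale relative to the 75th percentile of each array. This was a 23.5-fold lower level, with a log2 difference of -4.55 ± 0.70 (SE, limma adjusted p = 4.16e-06). By their brightest probes miR-551b was 21.1-fold lower, let-7a 13.2-fold and let-7f 11.1-fold. miR-370, encoded in the imprinted cluster of chromosome 14, was 10.7-fold lower, from -1.23 ± 1.12 in control to -4.66 ± 0.93 in myeloma (limma adjusted p = 1.07e-07). The other members of this top group were let-7b, miR-34a, let-7d, let-7g and miR-214, which were between 9.53-fold and 7.46-fold lower. Adjusted p-values of these 10 miRNAs were at most 4.73e-05. The size of a difference depended on the probe: the other detected probes of miR-551b had log2 differences of -0.33 and -2.80, against -4.40 for the brightest, and that of miR-214 -0.27 against -2.90. Of the 176 other detected probes of miRNAs past the threshold, 66 gave a difference smaller by over 1.5-fold and 15 one larger by over 1.5-fold. For each of the 10 miRNAs at most 1 of the 20 myeloma arrays lay above the control mean, and for let-7a, miR-370, let-7d and let-7g none did. The sizes rested on days C and D: on day B only miR-370 and let-7b of the 10 passed, with log2 differences of -2.71 and -1.47, while miR-195 had -1.08 (limma adjusted p = 0.104), let-7a -0.87 and miR-214 -0.61.

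Increases reached 3.79 ± 0.69 (SE) on the log2 scale for miR-198 (limma adjusted p = 3.54e-05), from -4.81 ± 0.90 (SD, n = 8) in control to -1.02 ± 1.97 (SD, n = 20) in myeloma. miR-939 was higher by 3.59 ± 0.47 (SE) and miR-936 by 3.30 ± 0.48 (SE), with adjusted p-values of 5.77e-07 and 1.86e-06. The remaining 7 of the 10 largest increases were miR-940, miR-134, miR-575, miR-135a*, miR-1308, miR-630 and miR-663, with log2 differences from 2.83 down to 2.27. The increases were uneven over scan days: on day B miR-198 had a difference of 0.53 (limma adjusted p = 0.353), miR-1308 of -0.18 and miR-663 of 0.74, none past the threshold. On the shared print design miR-134 and miR-630 had differences of 0.63 and 0.69. All 20 myeloma arrays lay above the control mean for miR-939, miR-936, miR-134, miR-135a* and miR-630. The entry miR-1308 has since been regarded as a fragment of transfer RNA rather than a miRNA.

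**Figure D2:**
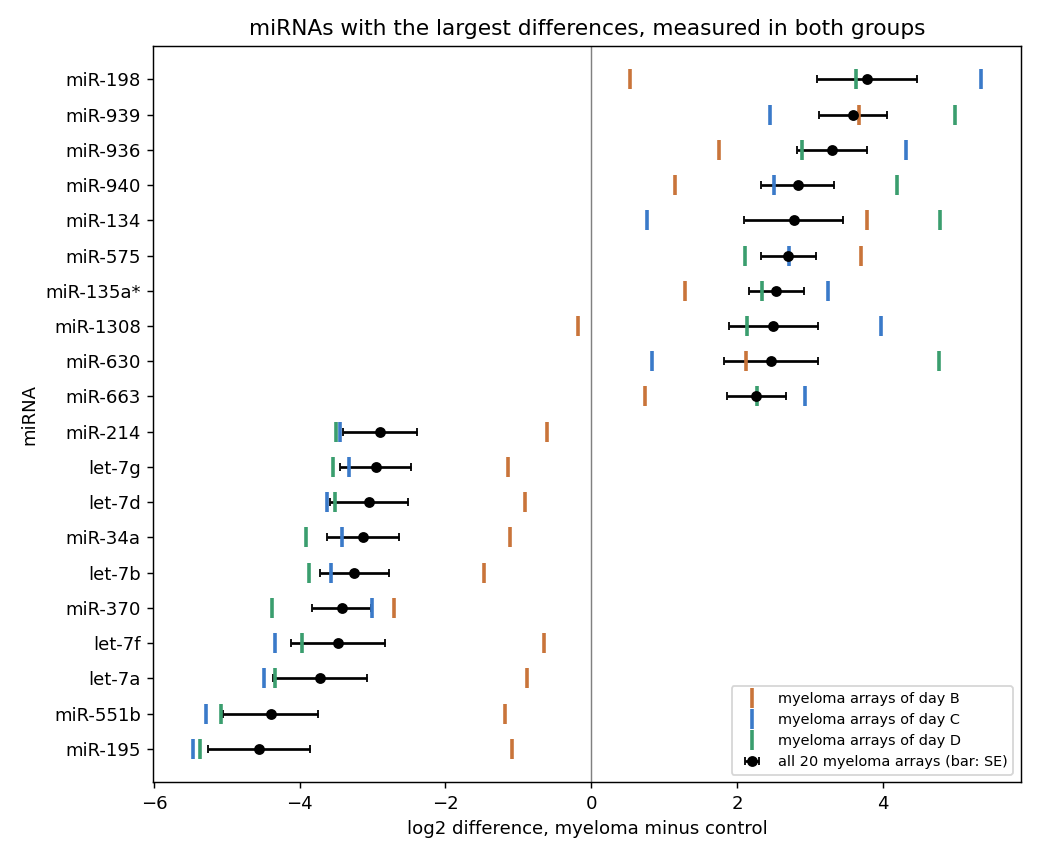
Log2 difference between myeloma and control (x axis) for the 10 largest decreases and 10 largest increases among miRNAs measured in both groups (y axis). Black points are the mean over all 20 myeloma arrays with their SE, and coloured ticks are the myeloma arrays of each scan day against the 8 control arrays, with miR-195 at -1.08 on day B and -5.47 on day C.

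Some miRNAs were measured mainly in 1 group. miR-1288 was not well above background on any control array and was measured on 18 of 20 myeloma arrays. It passed the test (limma adjusted p = 5.11e-06) and was 4.43-fold above the lowest control signal that was well above background. By the same measure let-7d* was 4.90-fold higher, measured on 17 myeloma arrays, and miR-1181 5.26-fold higher, measured on 15. The log2 difference of let-7d* was 0.54 on day B (limma adjusted p = 0.45) and 2.27 and 3.92 on days C and D. That of miR-1181 was -0.0001 on day C and 4.08 and 5.10 on days B and D. These folds set the mean of the myeloma arrays against the lowest signal that was well above background on each control array. Myeloma signals below the floor entered that mean at the floor, so the folds are not strict lower bounds. miR-186 was measured on 1 control and 19 myeloma arrays and was higher by 2.32 ± 0.24 (SE) on the log2 scale, and miR-1469 was measured on 2 and 17. In the other direction let-7e was measured on all 8 control and 6 myeloma arrays and was 7.28-fold lower in myeloma. miR-199b-5p, measured on 7 myeloma arrays, was 7.09-fold lower. miR-342-5p, miR-505* and miR-152 were each measured on 8 of the 20 myeloma arrays, and were 3.89-fold, 3.76-fold and 3.67-fold lower. With normexp background correction miR-342-5p and miR-505* did not pass and their differences were 0.03 and 0.06.

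The 11 miRNAs that passed with slide as a random block were miR-939, miR-936, miR-186 and miR-1280, which were higher in myeloma, and miR-195, miR-551b, miR-370, let-7e, miR-199b-5p, miR-342-5p and miR-505*, which were lower. Their adjusted p-values in that model ranged from 0.0448 to 0.0492. All 191 differences kept their sign in it. On the print design shared by both groups 216 miRNAs passed, 95 higher and 121 lower, and 169 of the 183 main calls tested there passed in the same direction.

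Families of related sequence were described next, from lists fixed before the data were examined. All 9 let-7 family members that were tested fell, with a median log2 difference of -2.96 (camera adjusted p = 0.000284), a call that was lost with an estimated correlation (adjusted p = 0.432) and held with slide as a random block (adjusted p = 3.17e-05). let-7i was 6.42-fold lower and let-7b 9.53-fold lower. All 7 members of the miR-15/16 family also fell, with a median of -1.91 (camera adjusted p = 0.00766), a call that was likewise lost with an estimated correlation (adjusted p = 0.432) and held with slide as a random block (adjusted p = 0.00593). They included miR-15b, 5.65-fold lower, miR-16, 2.89-fold lower by its brightest probe, and miR-503, 2.28-fold lower and measured on 5 control and 4 myeloma arrays. The other detected probe of miR-16 had a log2 difference of 0.50. Members of this family repress cyclins and BCL2. Both medians were below 0 under every scaling tried, while miR-503 had a difference of 0.22 with normexp background correction. The drop was uneven over scan days: the median of the let-7 list was -0.87 on day B, -3.44 on day C and -3.52 on day D, each against the same 8 control arrays. The median of the miR-15/16 list was -1.08, -2.21 and -2.90 on these days, and on day B 2 of the 7 members had differences above 0, miR-424 at 0.25 among them, while miR-195 and miR-15a did not pass.

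Both lists that describe kinds of array entry were higher in myeloma. Entries listed in advance as GC-rich and often bright at low RNA input, a label not checked here, had a median log2 difference of 1.25 (camera adjusted p = 0.0431). Of these, 13 of 24 were higher, 3 lower and 8 not past the threshold. This call was lost with an estimated correlation (adjusted p = 0.432). Besides miR-939 and miR-575 they held miR-1471, higher by 2.19 ± 0.30 (SE), and, against the trend, miR-671-5p, which was 6.22-fold lower. Entries derived from other small RNAs had a median of 1.19 (camera adjusted p = 0.0431), with 6 of 7 higher. This call, too, was lost with an estimated correlation (adjusted p = 0.432). The median of this list was 0.46 on day B, 2.17 on day C and 1.005 on day D. Among its members miR-1280 was higher by 2.14 ± 0.27 (SE) and miR-720 by 1.14 ± 0.26 (SE). Both calls held with slide as a random block (adjusted p = 0.0278 for each). With scan day as a random block the list of entries from other small RNAs did not pass (adjusted p = 0.0844), while the GC-rich list did (adjusted p = 0.0142). On the shared print design the GC-rich list did not pass (adjusted p = 0.213). Both adjusted p-values were 0.0514 with quantile normalization and 0.0888 with the total signal. Random regroupings of the 28 arrays called at least 4 lists in 26 of 100 splits, the real one included.

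**Figure D3:**
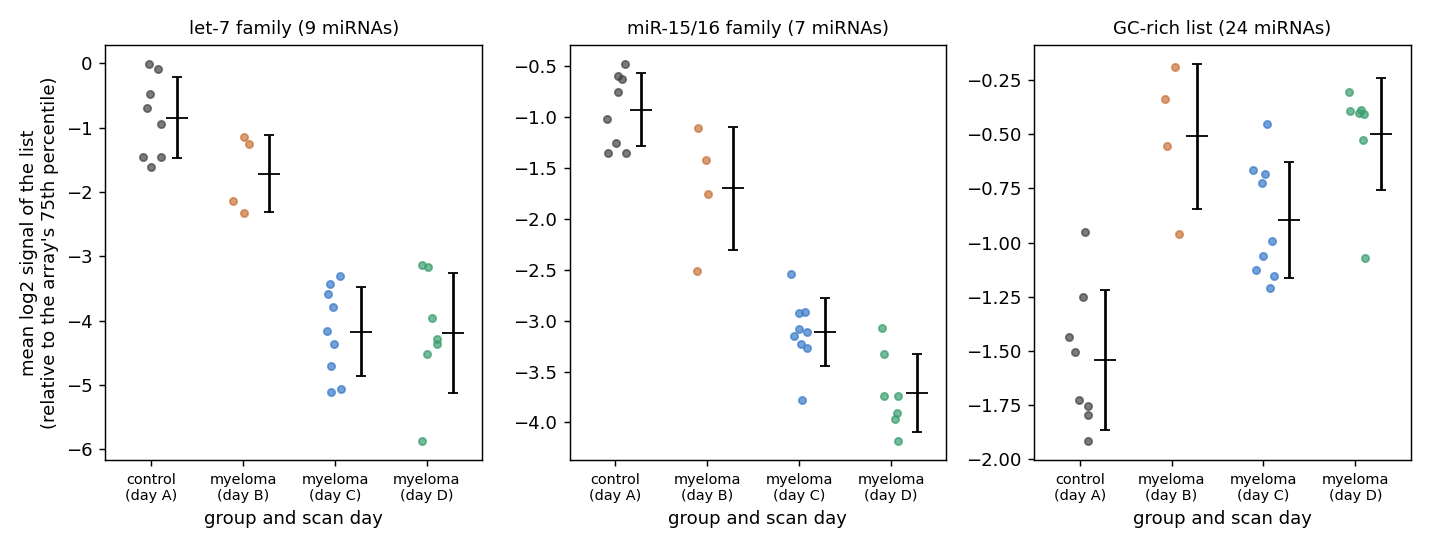
Mean log2 signal of 3 lists on each array (y axis, relative to the 75th percentile of that array) by group and scan day (x axis), with 1 point per array and black bars for the mean and SD of each day. The let-7 list averages -0.84 in control, -1.72 on day B, -4.17 on day C and -4.19 on day D.

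Lists of cell types that could shed RNA into marrow fluid were examined for the make-up of the samples. Of the 11 tested miRNAs of mesenchymal stromal cells, 7 fell and none rose, with a median of -1.19, and the list did not pass the threshold (camera adjusted p = 0.0573). It passed with slide as a random block (adjusted p = 0.0278) and on the shared print design (adjusted p = 0.00537). It did not pass with scan day as a random block (adjusted p = 0.0844) or with an estimated correlation (adjusted p = 0.739). Its members miR-214 and miR-199b-5p are named above, and miR-100 was 3.21-fold lower. Its median was 0.12 on day B and -1.84 on day C. The median of this list was 0.0003 with normexp background correction.

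Of 7 myeloid miRNAs, 4 fell and none rose (camera adjusted p = 0.2). None of the 4 passed on day B, where the median of the list was -0.12, against -0.70 on day C and -1.90 on day D. miR-223, the main miRNA of neutrophils and monocytes, was 4.52-fold lower, miR-424 was 4.13-fold lower and miR-27a 2.06-fold lower. Of 10 lymphoid miRNAs, 1 was higher, 2 were lower and 7 did not pass (camera adjusted p = 0.612). miR-146a, a brake on NF-kB signalling, was higher by 2.13 ± 0.33 (SE), while miR-155, which is induced on lymphocyte activation, was 3.21-fold lower, with a difference of -0.16 on day B (limma adjusted p = 0.766). Of 9 red cell miRNAs, 2 were higher and 4 lower (camera adjusted p = 0.441). miR-451, the most abundant red cell miRNA, did not differ beyond the spread (log2 difference 0.07 ± 0.44, SE, limma adjusted p = 0.9). miR-486-5p was higher by 2.24 ± 0.60 (SE), with a difference of 0.27 on day B, whereas miR-486-3p, from the other arm of the same precursor, was 2.40-fold lower, and miR-183 was 3.08-fold lower, with a difference of 0.02 under normexp. Of 8 platelet miRNAs, 1 was higher and 2 were lower (camera adjusted p = 0.612). miR-199a-3p was lower (log2 difference -1.85 ± 0.46, SE) and miR-151-5p was 2.71-fold lower. miR-339-3p was 2.77-fold higher by the measure used for let-7d*, with a difference of 0.03 on day C. It was measured on no control array and on 15 myeloma arrays. Of 7 endothelial miRNAs, 3 were higher (camera adjusted p = 0.441), namely miR-222 by 2.02 ± 0.45 (SE), miR-221 by 1.53 ± 0.43 (SE) and miR-296-5p by 1.35 ± 0.33 (SE). miR-222 was measured on 2 of the 8 control arrays, and miR-221 had a difference of 0.18 on day B.

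miRNAs linked to myeloma were mixed. Of 13 tested miRNAs that earlier work reported as raised in myeloma plasma cells, 2 were higher and 5 lower (camera adjusted p = 0.441), and of 8 reported as lowered, 4 were lower and none was higher (camera adjusted p = 0.2). The list of the miR-17-92 and paralogous clusters, which promote proliferation, had 2 of 13 members higher and 5 lower (camera adjusted p = 0.417). Its members miR-20a, miR-17 and miR-106b were 4.86-fold, 2.81-fold and 2.63-fold lower. For miR-17 the mean over all its probes gave a log2 difference of 0.11, opposite in sign to that of its brightest probe. Another detected probe also went the other way for miR-16, miR-21, miR-27a, miR-151-5p and miR-486-3p. Of 4 miRNAs that respond to p53, 3 were lower (camera adjusted p = 0.163), with miR-34a 8.76-fold lower and miR-192 2.50-fold lower by their brightest probes. Their other detected probes had log2 differences of -1.01 and -0.08, against -3.13 and -1.32.

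Among the miRNAs to be reported whatever their result, miR-15a was 2.04-fold lower (limma adjusted p = 0.0178). miR-21, a miRNA raised in many tumours, was 2.24-fold lower by its brightest probe (limma adjusted p = 0.00509) and had a log2 difference of 0.31 by the mean over its probes. miR-29b, which represses collagen genes, had a log2 difference of 0.74 ± 0.46 (SE, limma adjusted p = 0.159), and miR-210, induced by low oxygen, -0.04 ± 0.22 (SE, limma adjusted p = 0.899). miR-135b was not well above background on any of the 28 arrays.

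The remaining lists gave no call. The miR-30 family had 2 of 7 members higher and 2 lower (camera adjusted p = 0.612), with miR-30d higher by 2.11 ± 0.38 (SE) and miR-30e by 1.26 ± 0.36 (SE). The lower members were miR-30a* and miR-30e*, with log2 differences of -1.21 and -1.02. On the shared print design miR-30e did not pass (log2 difference 0.43, limma adjusted p = 0.258). The imprinted cluster at 14q32 had 1 of 6 members higher, which was miR-134, and 1 lower, which was miR-370 (camera adjusted p = 0.612). The primate-specific cluster at 19q13 had 1 of 4 higher, miR-516b (camera adjusted p = 0.441). Lists with fewer than 4 tested members entered no list test. In the miR-29 family 0 of 3 passed, with a median of -0.21 and a mean of 0.05. Of the miRNAs that target RUNX2, 0 of 3 passed. The liver list had 1 tested member and the muscle list 1, both lower, the brain list had 1 of 2 lower, and the epithelial miR-200 list had 0 tested members. For each of the 23 lists the counts adjusted over the list alone were the same as those adjusted over all miRNAs.

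Because day and group overlapped, each scan day of myeloma was also set against the 8 control arrays, a comparison chosen after the data were examined. It called 146 miRNAs for day B, 195 for day C and 221 for day D. Of these, 67 passed on all 3 days in 1 direction, 32 higher and 35 lower. They included miR-939, miR-936, miR-575, miR-135a*, miR-146a, miR-222 and miR-186 among the higher, and miR-370, let-7b, let-7i, miR-15b, miR-16, miR-20a and miR-17 among the lower. For miR-16 and miR-17 this holds for the brightest probe, while their other detected probes went the other way in the main comparison. Of the 62 named miRNAs past the threshold that were followed here, 25 did not pass on day B, 5 on day C and 2 on day D. None of the 62 passed in the opposite direction on any day. miR-30e*, chosen by the same rule but not counted among the 62, did so. Its log2 difference was -1.02 in the main test (limma adjusted p = 0.04) and 1.16 on day B (limma adjusted p = 0.00283). Besides those given above, the 25 included miR-199a-3p, miR-199b-5p, miR-151-5p, miR-100, miR-21 and miR-720. Those of day C were miR-15a, miR-27a, miR-30e, miR-1181 and miR-339-3p, and on day D miR-296-5p and miR-1469. The days shared their controls: independent lists of these sizes would overlap in 15.9 miRNAs, unchanged groups simulated against the same controls gave a median of 0, and with the control arrays split 3, 3 and 2 between the days a median of 21 remained (range 15 to 36). Groups simulated with scan day effects of the observed size and no difference between phenotypes gave a median of 34 such miRNAs, with a highest value of 51, and a median of 107 calls in the main test.

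The size of differences between slides within the myeloma group was measured for comparison, with no difference in phenotype label. The 4 arrays of the slide read on day B differed from the other 16 myeloma arrays in 136 of 319 tested miRNAs. The 5 arrays of the largest slide of day C differed from the other 15 in 36 of 306, and the 7 arrays of day D differed from the other 13 in 84 of 301. With the total signal per miRNA in place of the spot signal the day B count was 80 and the day C count 70. Over the 3 myeloma days 217 of the 306 miRNAs differed (limma F test). These slides also held different samples.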

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

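In this part the random splits for the main count were set before their result was seen; the tests of signal, probe ratios, slides, scan day means, other probes, and the random splits for lists and slides were chosen after the result was seen.

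The number of miRNAs detected per array and the 75th percentile of signal stood apart in the same control array. Its gap to the next control array was 0.767 of the range for detected miRNAs and 0.655 of the range for the percentile, above the 95% limit of the Dixon test for 8 samples. Of 59 control values checked, these 2 passed the limit, and chance passes about 1 in 20. Without this array 181 miRNAs passed the main test, a run added after the data were examined.

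4 spike-in control RNAs, which the comparison of the groups does not use, gave a signal on all 20 myeloma arrays above every control array. Their mean signal was higher on the myeloma arrays by 10.8-fold for dmr_3, 34.9-fold for dmr_6, 34.9-fold for dmr_285 and 5.59-fold for dmr_31a. The SD within a scan day was at most 0.78 on the log2 scale for these 4 RNAs. Other control entries did not all go this way: mr_1 had a mean log2 signal of 9.62 on day A and 7.80, 9.25 and 6.98 on days B, C and D, and hur_6 of 8.41 on day A and 6.84, 6.36 and 4.15. The log2 ratio of dmr_6 to dmr_3 was -2.12 ± 0.23 (SD) on day A and -0.74, -0.21 and -0.52 on days B, C and D. The amounts added are not given in the sources used here.

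The 191 miRNAs past the threshold were above what random splits of single arrays gave. Of 100 splits 1, the real one, reached that number, and the highest other gave 9. The control group is 1 whole scan day, while random splits break the scan days up. They exclude a chance assignment of single arrays, but not chance effects of whole scan days. Simulated scan day effects with no difference between phenotypes gave a median of 107 calls. Less RNA signal in 1 group was argued against, since for 100% of the 191 calls the shift predicted from signal, its slope on the log2 scale factor (the 75th percentile of each array) within scan days times the difference in that factor (0.03, 95% interval -0.51 to 0.61), had a limit under 50% of the difference. Differences between slides may account for much of the count: 11 calls were left with slide as a random block, and a slide of the myeloma group alone differed from the rest in up to 136 miRNAs. Hybridisation or washing that differed between slides is a candidate explanation too, because on 1 array 2 probes of the same miRNA should keep their ratio, and in 73.3% of 60 such probe pairs (44 pairs, or 25 with slide as a random block) that ratio differed between the groups, and in 41 it differed among the myeloma scan days. The phenotype itself and end variants of the miRNAs stay open as untested, and group and slide cannot be told apart in this design.

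The direction of the lower let-7 and miR-15/16 lists as a whole does not rest on a single probe per miRNA. Of the 14 other detected probes of their members, 92.9% were lower in myeloma too. The exception was miR-16, whose other detected probe had a log2 difference of 0.50 against -1.53, so its direction rests on its brightest probe. These probes lie on the same arrays, with the same slides and scan days. Cross-hybridisation between family members was not checked, so the probes are not independent support. The size does depend on the probe, with a median of -1.61 by the other probes of the let-7 members against -2.96, and of -0.9996 by those of the miR-15/16 members against -1.91. Slides or scan days may carry a large part: within myeloma the scan day means of the let-7 list differed by 2.47 on the log2 scale, against a difference of -2.84 between myeloma (-3.68) and control (-0.84), and those of the miR-15/16 list by 2.01. On day B the let-7 list was at -1.72 ± 0.60 (SD, n = 4), against -0.84 ± 0.63 (SD, n = 8) in control. Different samples were read on different days, so that differences between the samples and the phenotype stay open, both untested.

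For the higher GC-rich list, the shift predicted from raw signal was small. For the reason given for the 191 calls, this cannot decide whether the myeloma arrays had less RNA. The slope of the list mean on the log2 scale factor within scan days (-0.06), times the difference in that factor, predicted a shift of -0.0018 with a 95% interval of -0.09 to 0.0352 when arrays were drawn again within each group, against an observed difference of 0.86. Differences between slides cannot be told apart from the phenotype here: the scan day means within myeloma differed by 0.40, which is neither small nor large beside 0.86, and each day lay above the control mean. The count of lists past the threshold is weaker evidence than the single miRNAs. 26 of 100 splits of the arrays gave at least the real 4 lists and the highest other gave 8, so chance cannot be excluded for the number of lists.

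The differences between slides of the myeloma group were set against random splits of the 20 myeloma arrays. For the slide of day B 1 of 100 splits, the real one, reached 136 calls (highest other 27). For the slide of day D 1 of 100 reached 84 (highest other 40). A chance assignment of single arrays can be excluded for both. Chance effects of whole slides or scan days cannot, since the random splits break these up. For the slide of day C 2 of 100 splits, the real one included, reached 36 calls, and the highest other gave 89. That split put 3 of the 4 arrays of day B among its 5 arrays, and so points to a structure of the samples by scan day.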

How the results depend on the processing

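The runs with scan day as a random block and without the dimmest control array were chosen after seeing the data. Of the 191 miRNAs past the threshold, 94 higher and 97 lower, the count moved by more than 1.5 times in these settings, and the cause was not tested except where given: normexp background 80 (50 higher, 30 lower); detection on all arrays of a group 116 (46 higher), where 189 miRNAs were tested; slide as a random block 11 (4 and 7); scan day as a random block 0 (0 and 0). The deposited log2 values gave 56 higher. The remaining settings without a replicate block stayed within 1.5 times in total count, up to 228 with array weights, and no main call passed in the opposite direction in any setting. 3 sample numbers occur in both groups, and the deviations of these pairs correlated at 0.28, 0.08 and 0.25. By this correlation with the control array, the myeloma array of the same number ranked 1, 5 and 4 among all myeloma arrays. These values cannot decide on pairing, and the numbers were not taken as pairs in the main test. With the sample number as a fixed replicate block 43 miRNAs passed (29 higher, 14 lower). There hsa-miR-1308 (-0.26), hsa-miR-221 (-0.19), hsa-miR-21 (0.0107) and hsa-miR-451 (-0.93) changed sign. In that fit only the 3 shared numbers inform the difference. It thus compares 3 control with 3 myeloma arrays, and its count cannot be set beside the 191 of the whole comparison.

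Of the same 62 named miRNAs past the threshold that were followed over scan days, 33 kept direction and side in every setting without a block. Signs changed with normexp for hsa-miR-342-5p (0.0251), hsa-miR-505* (0.0602), hsa-miR-183 (0.0181), hsa-miR-503 (0.22) and hsa-miR-210 (0.24), and with the mean over probes for hsa-miR-17 (0.11), hsa-miR-21 (0.31) and hsa-miR-210 (0.31). hsa-miR-210 and hsa-miR-451, near 0 in the main result, also changed sign: hsa-miR-210 with no scaling (0.0701), slide as a random block (0.0118), without slide C (0.0085) and without the dimmest control array (0.0285), and hsa-miR-451 with total signal (-0.15), the 75th percentile over all probes (-0.21), quantile normalization (-0.42), median scaling (-0.22), the authors' table (-0.60), without slide D (-0.13), without slide F (-0.0745) and scan day as a random block (-0.0568).

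Of the 4 lists past the threshold, 0 passed with an estimated correlation, 2 with quantile normalization, 2 with total signal and 3 with scan day as a random block, where the list of entries from other small RNAs was lost (adjusted p = 0.0844). The miR-30 list (adjusted p = 0.466) and the 14q32 list (adjusted p = 0.511) turned direction on the control print design, and the latter with total signal (adjusted p = 0.995). With total signal the contrasts within myeloma gave 80 calls for slide B and 70 for slide C. Signal over background limits the low miRNAs: the floor lay at -6.86 on the log2 scale.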

Other observations

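The test of precursor arms in this part was chosen after the signs of several pairs had been seen.

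Both arms of 1 precursor were tested for 40 precursors. If the level of a precursor set the level of both arms, they would be expected to move together. They did so in 20 of the 40, or 50%, which is the number that random pairing gives on average (19.96 of 40, one-sided permutation p = 0.62). Among the 14 precursors with both arms past the threshold, 4 moved in 1 direction and 10 in opposite directions. let-7d fell by 3.05 on the log2 scale, while let-7d*, measured on no control array, was 4.90-fold higher by the measure given above. miR-486-5p was higher and miR-486-3p lower by its brightest probe. These pairs were picked after their values were seen. A common change of precursors is thus not visible in these data; arms may differ in stability in fluid, but the value of 50% does not separate this from differences between probes.

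Arrays of 1 scan day had a median correlation of 0.944 over the tested miRNAs. Myeloma arrays of different days had a median of 0.816, and control and myeloma arrays 0.758.

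The print design of day D also carried 88 entries for viral miRNAs, on 7 myeloma arrays and no control array. Of these entries 20 were detected on at least 1 array and 10 on all 7. No control array measured them, so that no comparison was made.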
